A study of Drosophila melanogaster with 2 samples.

How the data were processed

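Chromatin immunoprecipitation followed by sequencing was performed on whole Drosophila melanogaster embryos of mixed sex, collected 0 to 20 h after egg laying, from a transgenic line that stably expresses CG17568 with a green fluorescent protein at its C terminus. The labels give 2 biological replicates of this 1 group, numbered 1 and 2, and sonicated fragments of 200 to 800 bp. The labels conflict on what was sequenced. The assay is given as transcription factor ChIP-seq and the antibody field names CG17568, while the free text of both samples calls them input controls. Both were treated as ChIP samples, on the strength of the assay title and of the IDR peak lists made from them, and the values hold only if that reading is right. The control experiment that the labels point to was not analysed here.

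The starting material was 4 peak lists deposited by the authors on the dm6 genome. The authors called peaks on each replicate and on both replicates pooled, which gave 3 relaxed lists of 30000 peaks each, meant as input for the irreproducible discovery rate (IDR). From these lists they made an IDR-thresholded list of 3396 peaks. Another input file, shared by all lists, has no stated role. The IDR procedure makes use of how reproducible peak ranks are between replicates. The list made here holds the 3396 pooled relaxed peaks of highest signal, so a single peak in it need not be reproduced in both replicates. The text deposited with the lists gives their format as narrowPeak, in which each peak carries a signal value, a score of the authors' peak caller with no stated scale. The deposited lists also give the −log10 q-value of each peak and the offset of its summit. The column for an unadjusted p-value held -1 in every row. The peak caller, the aligner, their versions and the IDR threshold are not given in the sources used here. The files hold no read counts, so the sequencing depth of each replicate is unknown. The signal values were used only to rank peaks within a list.

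Summits were placed on the Release 6 reference genome, the same build as dm6, and annotated with the Ensembl release 115 gene models (BDGP6.54), without transposable elements. A promoter summit was a summit within 500 bp of any annotated transcription start site (TSS), and a promoter was called bound when an IDR summit lay within that window. Each summit was also given 1 feature, in the order 5' UTR, CDS, 3' UTR, other exon, intron, intergenic. The background was the 25862 pooled relaxed peaks with no IDR summit within 500 bp. These peaks were candidates for the IDR list, but all had a lower signal than any peak in it. Promoter, feature and chromosome arm shares were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over features and over the 6 arms with peaks. Wilson 95% intervals are given for shares. Peaks and genes are the units of these tests and not replicates, so p-values and intervals cover counting error only.

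The 19 gene lists were tested by Fisher's exact test, two-sided, for the share of bound promoters. The background for coding lists was the 4077 protein-coding genes with a pooled relaxed summit within 500 bp of a TSS, and for tRNA, snRNA and snoRNA genes it was all annotated genes. Adjustment was over the 16 lists with a member in the background. The 16 known motifs were sought on either strand within 50 bp of each summit. All 8-mers, merged with their reverse complements, were tested within 50 bp of IDR summits against windows of equal width centred 300 bp to either side. A divergent promoter had a TSS of another gene on the opposite strand within 1000 bp upstream. The promoter share of the top and bottom signal quartiles was compared by a permutation test with 100000 resamples, and the upstream share of promoter summits by an exact binomial test, both two-sided. Replicates were compared through the share of the 3396 highest peaks of replicate 1 with a summit of replicate 2's 3396 highest within 100 bp. The same share was computed in 100 draws of random positions and of random peaks from the relaxed list of replicate 2.

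The gene lists covered cytosolic and mitochondrial ribosomal proteins, proteasome, translation initiation, tRNA, snRNA and snoRNA genes, replication histones, Hsp70, architectural proteins, Polycomb and Trithorax, Hox, segmentation, neural, mesoderm and muscle, dosage compensation, cell cycle, germline, and zinc finger proteins with a ZAD domain. The lists, motifs, tests, thresholds and the rule for named items were set before the data were examined. Named items were the 25 IDR peaks of highest signal with the gene of the nearest TSS, CG17568 itself, and up to 4 bound members of each list with the highest signal. For 8-mers, the 10 with the highest odds ratio were named among those with adjusted p under 0.05 at 1% or more of summits. The leading 8-mer was expanded to a position count matrix from matches with at most 1 mismatch. List members given under an older symbol were matched to the current symbol, and 0 listed symbols were left without a gene.

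The tests were tested on simulated data. In lists of 3396 peaks drawn at random from the background, the promoter, arm and quartile tests each made a call in 5 of 100 draws. The coding lists gave any call in 2 of 20 draws and the motifs in 0 of 20. The non-coding lists gave a call in 16 of 20 draws against all annotated genes, because 63.1% of tRNA genes and 28.9% of all genes had a relaxed peak within 500 bp. Among genes with a relaxed peak the non-coding lists gave a call in 1 of 20 draws, and that background was therefore added as an alternative. All 10 planted 8-mers and a planted gene list in 20 of 20 draws were recovered. The simulated summit and flank sequences had the same base composition, unlike the real ones, so 8-mer calls due to composition could not arise. In the draws with the planted gene list, genes were bound independently, without the shared summits of the real data. With promoter peaks weighted 4 to 3 against others in random draws, the promoter test called the excess in 20 of 20 draws, with odds ratios from 1.30 to 1.49.

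Alternatives were the upper 1698 IDR peaks by signal, the 3396 highest peaks of either replicate's own list, and TSS windows of 250 and 1000 bp. Others were a background of the 3396 relaxed peaks just below the threshold, random positions, all annotated genes, motif windows of 100 bp, flanks of the same peaks, relaxed summits matched by promoter class, and 6-mers. For replicate agreement, they were other overlap rules and other numbers of peaks. Where 1 replicate was left out, the background came from the relaxed list of the other. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.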

Results

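The binding sites of CG17568, a predicted zinc finger protein, were mapped across the genome of whole Drosophila embryos aged 0 to 20 h. The design has 1 group of 2 biological replicates and no other condition, so the comparisons are between the replicates and between the IDR peaks and the weaker peaks of the relaxed list. The labels conflict on whether the samples are ChIP or input, and they were read as ChIP. The IDR list held 3396 peaks with a median width of 396 bp, which together covered 1054 kb. Their signal values ran from 127 to 3471.7 with a median of 188, and their −log10 q-values from 2.09 to 3.20. All 3396 had the same summit and signal in the pooled relaxed list, in which exactly 3396 peaks reached the lowest IDR signal. The IDR list was thus the top of the pooled list by signal, and comparisons with the weaker peaks are of strong against weak signal. Read depth is unknown, since the lists carry no read counts.

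The strongest sites were the same in both replicates. All of the 25 highest peaks had a matching summit in both replicate lists, at rank 31 or better in replicate 1 and rank 30 or better in replicate 2. Among the 500 highest IDR peaks, 97.4% lay within 100 bp of a summit in the 3396 highest of both replicates. Over the whole IDR list this share was 66.5% (2257 peaks), while 94.5% (3209 peaks) had a summit within 100 bp in both full relaxed lists. Of the 3396 highest peaks of replicate 1, 67.0% were shared with the 3396 highest of replicate 2 (95% Wilson interval 65.4 to 68.6). Random positions gave a mean of 0.479% and at most 0.824% in 100 draws, and random peaks of the relaxed list of replicate 2 gave a mean of 10.2% and at most 11.7%. Across the 3209 IDR peaks found in both replicates, Spearman's rho of the within-list ranks was 0.698. This is a correlation across peaks, which are not independent replicates. The IDR peaks were also selected from both replicates pooled, so their shares in the replicate lists and this rho follow in part from that selection.

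The highest peak of the list, with a signal of 3471.7, lay on 2R from 16571571 to 16572030. Its summit at 16571807 was intergenic, 275 bp upstream of CG4927, and it ranked 1 in each replicate. The next was on 3R from 17002188 to 17002721 with a signal of 2297, 77 bp upstream of Sf3a1, which encodes a splicing factor subunit. The third, on 3L from 19590440 to 19590811 with a signal of 2222, was 87 bp upstream of CG14100. Of the 25 highest peaks, 17 had their summit within 500 bp of a TSS, and 12 of these 17 lay upstream. They included the promoters of Ugalt, a UDP-galactose transporter (35 bp upstream), CenG1A (92 bp upstream), the nuclear pore protein gene Ndc1 (43 bp upstream), CG18549 (134 bp upstream), CG1888 (243 bp upstream) and mRpL41 (132 bp upstream). Summits near PNPase, lncRNA:CR31840, CG9147, Archease and CG11309 were 77, 17, 13, 293 and 90 bp downstream of the TSS.

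Also among the 25 highest sites, the Trithorax gene trx had a summit 17 bp upstream of its TSS on 3R at 14286920 with a signal of 1611. The Polycomb gene ph-p had one 483 bp upstream of its nearest TSS on X at 2137338 with a signal of 1486, in an intron of the gene. The wing vein gene px had one 209 bp upstream of its nearest TSS on 2R at 22514308 with a signal of 1962. Sites among the highest 25 that lay farther than 500 bp from a TSS were near CG11050 (1035 bp downstream, intron), cbt (1396 bp upstream, in an intron of ush), jp (762 bp upstream), the kinase gene Lk6 (968 bp upstream, intron), brat (717 bp upstream, intron), Trl (1534 bp downstream, intron), sbb (20103 bp downstream, intron) and CG13323 (11917 bp downstream, intergenic). Trl encodes the GAGA factor. The gene of the protein itself, CG17568 (2L, 19179749 to 19181702), was not bound at this threshold. The nearest IDR summit was 15167 bp from a TSS of the gene and the nearest summit of the pooled relaxed list 12239 bp.

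IDR summits lay at promoters more often than weaker peaks did. Of the 3396 IDR summits, 1447 (42.6%, Wilson 95% interval 41.0 to 44.3) lay within 500 bp of a TSS, against 5060 of the 25862 background peaks (19.6%, 19.1 to 20.1). The odds ratio was 3.05 (Fisher's exact test, p = 1.4e-177). Random positions on the same chromosomes were at promoters in 13.4% of cases. Against the relaxed peaks just below the threshold the odds ratio was smaller, at 1.40 (Fisher's exact test, p = 1.4e-11). Summits in 5' UTRs made up 12.5% of the IDR list and 5.89% of the background (odds ratio 2.29, exact adjusted p = 1.0e-39). Coding sequence held 0.412% of IDR summits and 1.57% of background summits (odds ratio 0.259, exact adjusted p = 2.6e-09), while it made up 16.7% of bases. In 3' UTRs the shares were 1.53% and 4.53% (odds ratio 0.328, exact adjusted p = 1.3e-19). Introns held 54.7% and 56.7% (odds ratio 0.923, exact adjusted p = 0.0358), and other exons 3.03% and 2.39% (odds ratio 1.28, exact adjusted p = 0.0358). Intergenic shares of 27.8% and 29.0% did not pass the threshold (exact adjusted p = 0.171). At the far end, 536 IDR summits (15.8%) were over 5000 bp from any TSS.

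The promoter share was highest among the strongest peaks. In the top quartile by signal, 453 of 849 summits (53.4%, Wilson 95% interval 49.99 to 56.7) were at promoters, against 330 of 849 (38.9%, 35.6 to 42.2) in the bottom quartile. The difference of 14.5 percentage points had a permutation p of 1.0e-05, the smallest that 100000 resamples can give. The middle quartiles, at 37.7% and 40.5%, lay near the bottom one.

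**Figure D1:**
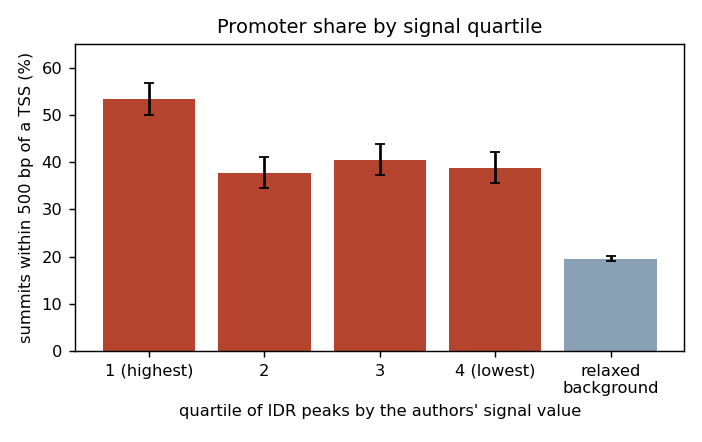
Share of summits within 500 bp of a TSS (percent, bars with Wilson 95% intervals) in each quartile of the 3396 IDR peaks by the authors' signal value, and in the relaxed background. The top quartile stands at 53.4%, the other quartiles at 37.7% to 40.5% and the background at 19.6%.

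At promoters the summits lay mostly upstream of the start site. The median signed distance to the nearest TSS was -94 bp (quartiles -204 and 54.5 bp) over 1447 summits. Of the summits not exactly on a TSS, 953 were upstream and 492 downstream, an upstream share of 66.0% (exact 95% interval 63.4 to 68.4, exact binomial p = 2.9e-34). Promoter summits of the background were upstream in 56.3% of cases (55.0 to 57.7), with a median of -41.5 bp. Bound promoters were also more often divergent. Of the 1406 protein-coding genes with a bound promoter, 747 (53.1%) had an oppositely oriented TSS within 1000 bp upstream, against 930 of 2671 genes (34.8%) with a relaxed peak only. The odds ratio was 2.12 (Fisher's exact test, p = 2.2e-29). A summit between 2 divergent TSSs can count for both genes, so the genes are not independent and this p overstates the evidence. Such a summit also lies upstream of both TSSs, so the upstream share and the divergent share are not separate results.

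**Figure D2:**
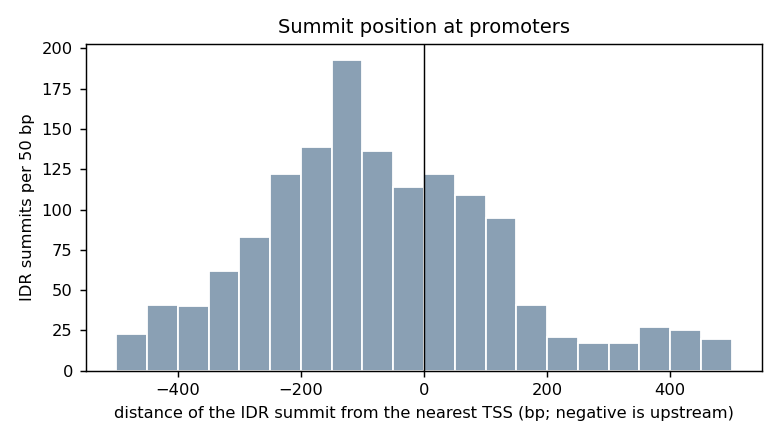
Number of IDR summits per 50 bp by signed distance from the nearest TSS in bp, negative upstream, for the 1447 promoter summits. The highest bin, with 193 summits, starts at -150 bp.

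Genes of the cytosolic ribosome were bound almost without exception among those that could be tested. Of the 54 cytosolic ribosomal protein genes with a relaxed peak at the promoter, 52 (96.3%) carried an IDR summit, against 1354 of 4023 other genes (33.7%). The odds ratio was 51.3 (Fisher's exact test, p = 3.1e-22, adjusted p = 5.0e-21 over 16 lists). The highest signals were at RpS27 (893, on 3R with the summit 19 bp upstream of the TSS), RpL31 (750, 2R, 20 bp upstream), RpL24 (709, 2L, 3 bp downstream) and RpS4 (650, 3L, 2 bp downstream). Summits at RpS27, RpL31, RpL24 and RpS4 all fell in an annotated 5' UTR. The annotation holds 93 genes of this list, and 39 of them had no pooled relaxed peak within 500 bp, among them RpL32, RpS3 and RpS6. The 2 testable genes without an IDR summit were RpL21 and RpS19b. These 5 genes were chosen after their values were seen. The odds ratio was 16.5 in the peaks of replicate 2 alone and 17.3 in those of replicate 1 alone, with adjusted p of 1.9e-19 and 2.4e-17 by Fisher's exact test. It was 28.0 with the upper 1698 IDR peaks and 11.7 among all protein-coding genes, where 52 of 93 were bound.

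No other list passed the threshold. For the genes of these lists the number in parentheses is the signal value of the highest IDR summit within 500 bp of a TSS. Mitochondrial ribosomal protein genes were bound in 10 of 23 cases (exact adjusted p = 0.876), with the highest signals at mRpS23 (1737), mRpL41 (1438), mRpL23 (873) and mRpS2 (442). The mRpS23 summit was the same as that of CenG1A. Proteasome genes were bound in 3 of 7 cases (adjusted p = 1 by Fisher's exact test), namely Rpt2 (signal 236), Rpn13 (173) and Rpn11 (146). Translation initiation factor genes were bound in 5 of 10 cases (exact adjusted p = 0.875), led by eIF4EHP (820), eIF3h (216), eIF4A (181) and eIF5B (150). The summits at eIF3h and eIF5B had no counterpart within 100 bp in the relaxed list of replicate 1.

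Among chromatin regulators, Polycomb and Trithorax genes were bound in 7 of 11 cases (63.6%, odds ratio 3.34, p = 0.0556, adjusted p = 0.445 by Fisher's exact test), with the highest signals at trx (1611), ph-p (1486), E(z) (410) and jing (215). For this list the odds ratio was 4.65 in the peaks of replicate 2 alone and 1.97 in those of replicate 1 alone (exact adjusted p = 0.0672 and 0.603). Architectural protein genes were bound in 4 of 7 cases (adjusted p = 0.777, Fisher's exact test): Chro (1305), Cp190 (559), Trl (218, another site, 318 bp upstream of a TSS) and BEAF-32 (139). Among patterning and tissue genes, 0 of 6 Hox genes (adjusted p = 0.532, Fisher's exact test) and 4 of 11 segmentation genes (adjusted p = 1, Fisher's exact test) were bound. The segmentation genes were bcd (210), hairy (183, hry in the annotation), hb (175) and slp2 (165). Bound neural genes were elav (893), Sox100B (168) and N (154), 3 of 9 in all. Bound mesoderm and muscle genes were tin (435) and htl (144), 2 of 10. In the cell cycle list 4 of 10 were bound, Dp (284, with no counterpart in replicate 1), E2f1 (193), CycA (158) and stg (155). In the germline list 2 of 5 were bound, piwi (231) and vas (132), and in the list of zinc finger proteins with a ZAD domain 1 of 2, pad (198). Each of these last 5 lists had an adjusted p of 1 by Fisher's exact test. Replication histone genes, Hsp70 genes and dosage compensation genes had no coding member with a pooled relaxed peak at the promoter and were not testable against that background. The 111 replication histone genes form 1 cluster on 2L without a pooled relaxed peak at any promoter, so the test among all protein-coding genes, which counts them as separate genes, is not interpreted for this list. Among all protein-coding genes, 0 of 6 Hsp70 genes and 0 of 5 dosage compensation genes were bound, each with an exact adjusted p of 1.

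**Figure D3:**
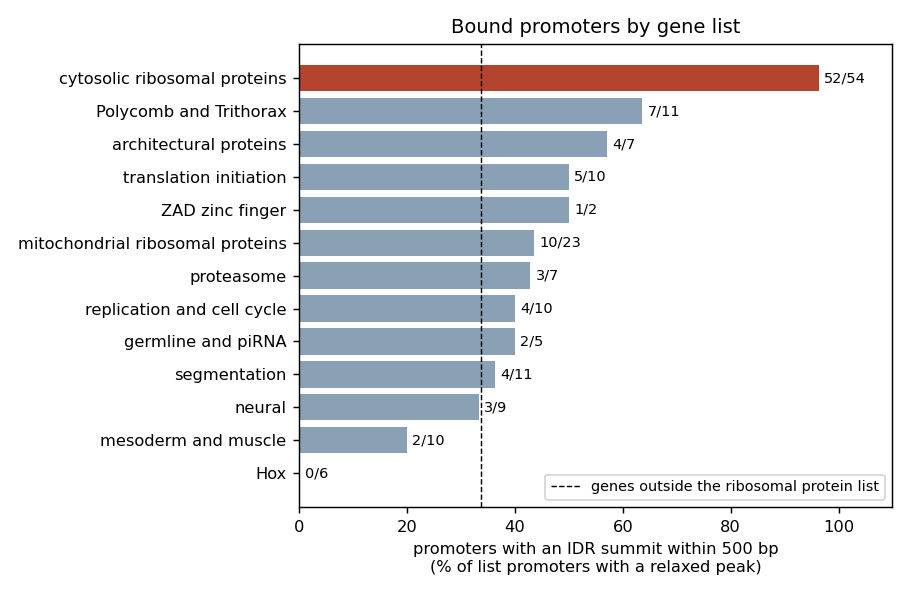
Percent of promoters with an IDR summit within 500 bp, among list promoters with a pooled relaxed peak, for each testable coding list, with bound over testable genes beside each bar. The dashed line marks the 33.7% of genes outside the cytosolic ribosomal protein list, and the darker red bar, at 96.3%, is the 1 list past the threshold.

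No excess of binding at non-coding RNA genes passed the threshold. For tRNA genes, 28 of 290 (9.66%) had an IDR summit within 500 bp against 8.91% of other annotated genes (odds ratio 1.09, exact adjusted p = 1), led by tRNA:Tyr-GTA-1-8 (860), tRNA:Phe-GAA-1-2 (570), tRNA:Arg-CCT-1-2 and tRNA:Arg-CCT-1-3 (327 for the summit they share). This direction turned when only genes with a relaxed peak were compared, with 28 of 183 tRNA genes (15.3%) against 31.4% (odds ratio 0.395, adjusted p = 9.6e-06, Fisher's exact test). The comparison with all genes is biased upwards for tRNA genes, 63.1% of which had a relaxed peak, against 28.9% of all genes. Neighbouring tRNA genes shared summits, 20 for the 28 genes. For snoRNA genes 17 of 269 (6.32%, exact adjusted p = 0.64) were bound, led by snoRNA:Or-aca5 and snoRNA:Psi28S-2949 (633 for a shared summit), snoRNA:Psi28S-1232 (570) and snoRNA:Me18S-C1096 (430). The summit at tRNA:Phe-GAA-1-2 and snoRNA:Psi28S-1232 is also that of RpL17, and the one at snoRNA:Me18S-C1096 that of RpL3, which had no counterpart within 100 bp in the relaxed list of replicate 1. For snRNA genes 2 of 32 were bound (exact adjusted p = 1), snRNA:U6:96Ac (139) and snRNA:U6:96Ab (132).

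Chromosome 4, the small and largely heterochromatic autosome, held fewer of the IDR peaks than of the background peaks. It carried 27 IDR peaks (0.795%) and 674 background peaks (2.61%), an odds ratio of 0.299 (Fisher's exact test, p = 2.6e-13, adjusted p = 1.5e-12). The density of IDR peaks was 20.0 per Mb on chromosome 4 and 22.3 to 30.0 per Mb on X and the major autosome arms. The background peaks numbered 500 per Mb on chromosome 4 and 157 to 227 per Mb elsewhere. The call was lost against the relaxed peaks just below the threshold (odds ratio 0.611, exact adjusted p = 0.167). X, 2L, 2R, 3L and 3R did not pass the threshold in the whole IDR list, with odds ratios from 0.939 to 1.11, and no list held a peak on Y. In the upper 1698 peaks 2R passed it (odds ratio 1.22, exact adjusted p = 0.00701), as did 3L (odds ratio 0.874, adjusted p = 0.0492). Both also passed in each replicate alone, with odds ratios of 1.15 and 1.19 for 2R and of 0.890 and 0.891 for 3L, and 3R passed in replicate 2 alone (odds ratio 1.12, exact adjusted p = 0.0123).

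Of the 16 known motifs, 7 differed between IDR and background summits. Of these calls, 6 were lost against the relaxed peaks just below the threshold, a background of 3396 peaks in place of 25862. Promoter summits made up 42.6% of IDR and 19.6% of background summits. In tests by class, chosen after the data were seen, 0 motifs passed at promoters and only CTCF and A tracts outside them. Odds ratios at promoters and outside were 1.21 and 1.04 for GAGA and 1.03 and 1.29 for the E-box CAGCTG. They were 1.27 and 1.10 for TATA, 1.75 and 1.76 for Zelda, and 1.84 and 2.94 for CTCF. The CTCF motif was found at 31 IDR summits (0.913%) and 0.363% of background summits (odds ratio 2.53, exact adjusted p = 2.7e-04). It was also higher than in the flanks of the same peaks (odds ratio 4.16, exact adjusted p = 1.3e-05), but equal to the peaks just below the threshold (odds ratio 1.00). The M1BP motif, a core promoter element, was at 10 IDR summits (0.294%) against 0.0580% (odds ratio 5.09, exact adjusted p = 0.00146), and it missed the threshold among promoter summits alone (odds ratio 2.63, adjusted p = 0.176) and against flanks (odds ratio 2.23, adjusted p = 0.223). Against the peaks just below the threshold the M1BP odds ratio was 5.01 without passing (exact adjusted p = 0.264). In the peaks of replicate 2 alone it was 2.81 (exact adjusted p = 0.0435), and in those of replicate 1 alone 4.43 (exact adjusted p = 0.00176). The TATA box (7.89% against 6.77%, odds ratio 1.18, exact adjusted p = 0.0465) and the Zelda motif (0.648% against 0.344%, odds ratio 1.89, adjusted p = 0.0349) were higher in the IDR list. TATA, a motif of mostly A and T, was also higher than in the flanks (4.52%, odds ratio 1.81, exact adjusted p = 1.9e-10). The flanks had a higher GC content than the summits (42.0% against 34.7%), and its effect on this excess was not tested. Zelda did not differ from the flanks past the threshold (odds ratio 1.13, exact adjusted p = 0.683). Against the peaks just below the threshold neither passed, with odds ratios of 1.07 for TATA (exact adjusted p = 0.676) and 2.21 for Zelda (adjusted p = 0.264). The calls for Zelda, TATA, GAGA and the E-box CAGCTG were lost in either replicate alone, in part with odds ratios near those of the whole list. In replicate 2 alone they were 1.60, 1.19, 1.22 and 1.24 (exact adjusted p = 0.137, 0.0517, 0.204 and 0.0618), and in replicate 1 alone 1.81, 1.03, 1.37 and 1.15 (exact adjusted p = 0.0628, 0.800, 0.0564 and 0.272). Over the whole IDR list, the GAGA motif (2.27% against 1.69%, odds ratio 1.35, exact adjusted p = 0.0496) was higher than in the background but lower than in the flanks (odds ratio 0.588, adjusted p = 1.4e-04). The E-box CAGCTG (4.15% against 3.27%, odds ratio 1.28, exact adjusted p = 0.034) was above the background, while its difference from the flanks did not pass the threshold (odds ratio 0.891, adjusted p = 0.457). A tracts were rarer at IDR summits than in the background (7.89% against 11.8%, odds ratio 0.640, exact adjusted p = 3.2e-11) but did not differ from the flanks past the threshold (odds ratio 1.14, adjusted p = 0.223). The DRE, BEAF, Su(Hw), Ohler 6, Ohler 7, Inr, Pho, CA repeat and Twist E-box motifs did not pass the threshold against the background. Against flanks 2 of them passed it, the CA repeat with 2.15% against 4.27% (odds ratio 0.493, exact adjusted p = 1.3e-07) and the Twist E-box with an odds ratio of 0.762 (adjusted p = 0.0242). In the upper 1698 peaks the CA repeat (odds ratio 0.607) and Inr (0.870) passed, each with an exact adjusted p of 0.0459, while GAGA (odds ratio 1.15), Zelda (1.72) and the E-box CAGCTG (1.03) lost their calls. With 100 bp either side of the summit BEAF (odds ratio 1.13), Ohler 7 (1.41), Inr (0.886) and Pho (0.738) passed and TATA (1.12) lost its call, and BEAF passed in replicate 1 alone (1.15).

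The sequence at the summits was rich in A and T. Within 50 bp of the summit the mean GC content was 34.7% ± 8.64 (SD over 3396 peaks), against 42.0% ± 9.97 in the flanks and 36.7% ± 8.27 at background summits. Of 32890 8-mers, 543 were more frequent and 212 less frequent at summits than in the flanks (Fisher's exact test with Benjamini-Hochberg adjustment). The test did not adjust for the difference in GC content between summits and flanks. How many of these calls come from base composition alone is therefore unknown. Of the 543, 333 were also called in the peaks of replicate 2 alone and 362 in those of replicate 1 alone. Against relaxed summits of the same promoter class, whose own base composition was not measured, 54 were more frequent, and 51 of these were among the 543. With 6-mers the balance turned, with 385 of 2080 more frequent and 820 less frequent than in the flanks. The highest odds ratio was for TAGGTAAA, at 39 summits (1.15%) and 0.221% of flanks (odds ratio 5.25, exact adjusted p = 2.9e-06). It was followed by AATATTGA (2.68%, odds ratio 4.89), ACCGGAAA (1.03%, 4.70), ATATTTAC (3.71%, 4.32), AATATTTG (4.53%, 4.31), TAATATCA (1.09%, 4.15), CACTGAGA (1.15%, 4.14), AGGTAAAT (1.21%, 4.14), ATCTTAAA (1.71%, 4.05) and ATATTGAC (1.15%, 3.93), where the second value in each case is the odds ratio. ACCGGAAA and CACTGAGA hold 4 G or C bases, TAGGTAAA, AGGTAAAT and ATATTGAC 2, and the others 1. The 10 are not separate sequences. AATATTGA and ATATTGAC overlap in all but 1 base, as do TAGGTAAA and AGGTAAAT, and AATATTTG and ATATTTAC share ATATTT. All 10 kept their calls in the peaks of each replicate alone, but the odds ratios moved. For ATATTGAC they were 6.06 in replicate 1 alone and 3.42 in replicate 2 alone. ACCGGAAA, TAATATCA, CACTGAGA and ATCTTAAA missed the threshold against relaxed summits of the same class, with exact adjusted p of 0.0592, 0.288, 0.221 and 0.0712. In that comparison all 10 odds ratios were smaller, at 3.27, 2.21, 2.41, 2.33, 1.78, 1.94, 1.96, 3.08, 1.89 and 3.12 in the order given. A match to TAGGTAAA with at most 1 mismatch was present near 495 summits (14.6%), against 8.63% of flanks and 10.9% of background summits. These matches were picked by their likeness to the 8-mer, so only the bases outside it are free to vary, and there no base exceeded 53.3%.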

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

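The motif comparisons within promoters and outside them, and the tRNA, snRNA and snoRNA comparison among genes with a relaxed peak, were tests chosen after the data were seen. The promoter excess, the quartile difference, the upstream position, the divergent promoters and the ribosomal protein list kept their direction and their side of the threshold under every alternative run for them. Leaving out 1 replicate gave 3.03 to 3.30 for the promoter odds ratio and 1.96 to 1.98 for divergent promoters. The authors' unknown read depth limits any statement on sites that were not called.

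The upper part of the IDR list by signal held 1698 peaks. Replicate agreement was 72.1% with any overlap of at least 1 bp, 61.8% with a reciprocal overlap of 50%, 72.8% over the 1698 highest peaks and 59.6% over the 6792 highest. The number of arms past the threshold was 3 in the upper part of the list, 3 to 4 with 1 replicate left out and 0 against the peaks just below the threshold, where the odds ratio for chromosome 4 was 0.611. The number of lists past the threshold was 2 against all annotated genes, 1 of them the replication histones, a single cluster without relaxed peaks whose 111 genes are not independent, and 2 with non-coding lists among genes with a relaxed peak, where the odds ratio for tRNA genes turned from 1.09 to 0.395 with a call. The number of motifs past it was 3 to 4 with 1 replicate left out, 1 against the peaks just below the threshold, 0 among promoter summits and 2 outside promoters. Apart from tRNA genes, the odds ratios that crossed 1 and had a call in at least 1 of the 2 analyses were GAGA at 0.949 and the E-box CAGCTG at 0.900 against the peaks just below the threshold, and, against flanks, GAGA at 0.588, CAGCTG at 0.891, A tracts at 1.14 and the Twist E-box at 0.762. More frequent 8-mers numbered 269 in the upper part of the list, which holds fewer peaks, and 54 against relaxed summits of the same class. For the other changes the cause was not tested. Among single lists, motifs, arms and 8-mers, 182 of 298 values kept their direction and their side of the threshold, 34 lost a call, 15 gained one and 64 crossed 1, of which 57 had no call in either analysis. The other 3 were counts of less frequent 8-mers that changed by more than 1.5 times.

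The 57 odds ratios that crossed 1 without a call were as follows. In the upper part of the list they were 0.962 for 3R, 0.658 for proteasome, 0.987 for translation initiation, replication and cell cycle, and germline genes, 0.657 for tRNA, 1.02 for snoRNA and 0.394 for segmentation genes, 1.37 for DRE and 1.22 for Ohler 6. Against the peaks just below the threshold they were 0.905 for 2R, 1.01 for 3L, 0.967 for 3R, 0.895 for BEAF, 0.690 for Ohler 7, 1.06 for Pho and 0.971 for the Twist E-box. With 250 bp around a TSS they were 0.563 for segmentation genes and 0.987 for replication and cell cycle and for germline genes, and with 1000 bp 1.46 for snoRNA and 0.790 for segmentation genes. Among all annotated genes they were 0.595 for proteasome, 1.79 for neural, 1.49 for mesoderm and muscle and 0.496 for ZAD genes. With 100 bp either side of the summit they were 1.19 for DRE, 1.30 for Ohler 6 and 1.04 for the CA repeat, and against flanks 1.12 for DRE, 1.43 for Su(Hw), 2.40 for Ohler 6, 0.870 for Ohler 7 and 1.08 for Inr. Promoter summits gave 2.33 for Su(Hw) and 1.09 for Pho, and summits outside promoters 0.981 for BEAF, 0.687 for Ohler 7 and 0.946 for the Twist E-box. Leaving out 1 replicate gave 0.975 to 1.01 for X, 0.990 to 0.999 for 2L, 0.926 to 1.48 for proteasome, 0.844 to 1.39 for translation initiation, 0 to 1.05 for snRNA, 0.793 to 0.985 for segmentation, 0.492 to 0.926 for replication and cell cycle and 0.370 to 0.985 for germline genes, 1.22 to 1.29 for DRE, 1.24 to 1.37 for Ohler 6 and 0.975 to 0.999 for the Twist E-box, where X, proteasome, translation initiation and snRNA genes crossed 1 in 1 of the 2.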

Other observations

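The tests on summit positions at ribosomal protein genes, on relaxed summits near list genes, on 8-mers by promoter class, on summits per gene and on regions without peaks, and the comparison with other housekeeping lists, were chosen only after the results were seen. At the 52 bound ribosomal protein genes the summit lay almost on the start site, with a median of 7.5 bp (quartiles -20 and 23 bp), against -131 bp (quartiles -234 and 8 bp) at 1354 other bound genes. Only the IDR summit of highest signal within 500 bp of a TSS was used for each gene, so a weaker summit nearer to the TSS did not count. This summit lay within 100 bp of the gene's own TSS at 51 of 52 (98.1%) and 367 of 1354 (27.1%). The odds ratio was 137 (Fisher's exact test, p = 5.4e-27). The other genes include some bound only through the summit of a neighbour, which widens their distances. Genes that share a summit are not independent, so the contrast and its p are overstated. Over all 1447 promoter summits, the median distance to the nearest TSS was -94 bp. Ribosomal protein promoters ranked from 75 to 3147 in the pooled list, with a median rank of 550.5.

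Counting relaxed summits within 2000 bp of list genes, the share that passed IDR was higher at 5 of 17 lists. It was 75 of 184 summits (40.8%) at ribosomal protein genes, 12 of 36 (33.3%, exact adjusted p = 0.00169) at architectural protein genes and 38 of 169 (22.5%, adjusted p = 2.3e-04) at Polycomb and Trithorax genes. Relaxed summits elsewhere passed in 11.1% to 11.3% of cases for these lists. With promoter and other summits as strata, the odds ratios were 3.91 (95% interval 2.85 to 5.37), 2.85 (1.41 to 5.78) and 2.30 (1.58 to 3.34). Mitochondrial ribosomal protein genes (21 of 89) and snoRNA genes (44 of 174) also passed, but the stratified interval of the former held 1 (0.931 to 2.55). The stratified odds ratio was 1.66 (1.17 to 2.36) for all snoRNA genes and 1.08 (0.679 to 1.71) for those away from ribosomal protein genes. At tRNA genes 40 of 360 summits passed (11.1%, odds ratio 0.979, exact adjusted p = 1), and the odds ratio became 0.621 (0.444 to 0.868) only with strata. Summits of 1 gene were counted separately, and jing, a Polycomb and Trithorax list gene, alone held 9 IDR summits. The p-values and intervals by summit therefore overstate the evidence. Counted by gene, the architectural and the Polycomb and Trithorax lists did not pass (adjusted p = 0.777 and 0.445, Fisher's exact test). By number of IDR summits inside the gene, kirre led with 15 over 394 kb, followed by bun with 14 over 91.1 kb and CG1677 with 13 over 125 kb. These counts are not corrected for gene length. Per 10 kb they were 0.381, 1.54 and 1.04, against 3.70 for CHES-1-like, with 10 over 27.0 kb.

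Of the 10 named 8-mers, 4 were rarer at promoter summits than at other IDR summits after adjustment: ATATTTAC (2.21% against 4.82%, exact adjusted p = 4.9e-04), AATATTGA (1.59% against 3.49%, adjusted p = 0.00257), AATATTTG (3.11% against 5.59%, adjusted p = 0.00257) and ATATTGAC (0.553% against 1.59%, adjusted p = 0.0128). ACCGGAAA went the other way (1.45% against 0.718%, adjusted p = 0.0667, Fisher's exact test), without passing. The 4 rarer 8-mers overlap in sequence, so their calls are not separate results. Base composition at promoter and other summits was not taken into account. Between neighbouring pooled relaxed summits, the interval on 2L from 21401472 to 21558567, which spans the replication histone cluster, contains 111 coding genes, and each replicate list has 1 peak in it. The interval on X from 1313191 to 1823279 contains 49 coding genes, with 2 peaks in replicate 1 and 4 in replicate 2.

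The excess of promoters among IDR peaks was weighed against base composition, since IDR summits had a lower GC content than background summits. Within deciles of summit GC content the odds ratio was 3.13 (lower 95% bound 2.90), against 3.05 without strata, so base composition at the summit did not account for the excess. No biological explanation was tested, because the design has 1 group.

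The low odds ratio of chromosome 4 was weighed in the same way. Within GC deciles the odds ratio was 0.281 (0.191 to 0.412), and among summits outside promoters it was 0.237 (0.133 to 0.421), so neither base composition nor a lack of promoter summits there accounted for it. IDR peaks were only slightly less dense on chromosome 4 than elsewhere (20.0 per Mb against 22.3 to 30.0). Background peaks were much denser there (500 per Mb against 157 to 227). The low odds ratio thus reflects mainly an excess of weak relaxed peaks on this chromosome and not a scarcity of IDR peaks. The call was also lost against peaks just below the threshold.

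For the ribosomal protein promoters, the odds ratio within deciles of promoter GC content was 50.6 (12.2 to 209), which argues against base composition. Strong transcription of housekeeping genes in general could raise ChIP signal at open promoters. The mitochondrial ribosomal protein, proteasome and translation initiation lists were therefore pooled for comparison. Of their 40 genes with a relaxed peak at the promoter, 18 were bound. The odds ratio of 1.62 (0.866 to 3.03) lies below the interval of the ribosomal protein list (12.5 to 211). Among all genes of the 3 lists, 13.7%, 6.25% and 11.4% were bound in the order given, against 55.9% of the ribosomal protein list. Expression levels were not analysed here, so an effect of very high transcription stays open. The hypothesis of the TCT initiator, a core promoter element of ribosomal protein genes, cannot be told apart. Outside the ribosomal protein list 5 of 18 promoters with the element were bound (odds ratio 0.757, 0.269 to 2.13), and the pattern searched for matched only 8 of the 54 ribosomal protein promoters, so the bound set beforehand (an interval that holds 1) was wrong, since a pattern that misses most of the promoters it is meant to find cannot exclude the element. The rule that the pattern must find most of them was set after this result was seen.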
